A study of Mus musculus with 12 samples.

How the data were processed

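RNA was sequenced from whole mouse uterus on gestational day 3.5, with 6 libraries from Sirt1-KO females and 6 from Sirt1 control females. Per the labels, the animals were 6 to 8 weeks old, embryos were flushed out before the uterus was frozen, total RNA went into a stranded kit after removal of ribosomal RNA, and the samples were separate biological samples. HISAT2 version 2.2.0, Partek and DESeq2 are named in the submitters' processing notes, with the genome builds GRCm38 and mm10. The annotation, the counting step and whether counting used strand are not given in the sources used here.

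The file used is a table of the authors' own comparison, with no value per library. Its mean levels are a signal on the authors' normalized scale, given in the deposited table as the mean over all 12 libraries and as the least-squares mean of each genotype. Per the file headers, the totals, maxima and geometric means are further scores of the same normalized values. The p-value of each gene and its step-up FDR were computed by the authors, and the file headers do not name the test that gave them. The ratio of Sirt1-KO to control, the fold change and its 95% limits were computed by the authors and are printed as deposited. Per the file headers, the log2 column is the log2 of that ratio. Because these are normalized pooled values, the depth of each library is unknown, and no spread between libraries could be computed. The 95% limits are the measure of error used throughout, and "adjusted p" is the authors' FDR wherever a single gene is given.

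The content of the table was tested before use. Its highest FDR was 0.0499 and its lowest absolute fold was 1.50, so it lists only genes under an FDR of 0.05 with a fold of at least 1.5. A gene that is not listed was therefore either not tested, above the FDR limit or under the fold limit, and these cases cannot be told apart from the table. The ratio of total to mean was 12 for every listed gene, which is the number of libraries. Step-up FDR values hold the rank of each gene and the number of tests. The number of tests was taken as the smallest whole number that gave nearly the largest share of genes a whole rank, within 0.01, and was 21344, with 93.2% of ranks whole. On 20 simulated tables of 21344 tests, this recovered the number of tests in 20 and the last rank, to the nearest whole number, in 20. An earlier version that read the number of tests from the top gene alone was correct in 19 of the 20 and was dropped, although it too gives 21344 in the deposited table.

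Coordinates are those of the table, on GRCm38. Of 8348 listed genes, 97.7% had a symbol in the GENCODE M21 annotation. Among 8135 listed genes that matched a single annotated gene, 99.4% had the same start, and the table's stop was the annotated end plus 1 in 99.4%, so ends are printed 1 lower, as the annotation gives them. Genes that share exon positions with another gene, on either strand, are uncertain because the use of strand in counting is not stated.

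Before the data were examined, 19 gene lists, 17 marker lists, the tests and the rule for named genes were fixed. Symbols of a list that the annotation did not carry were dropped as second names of genes already in it. The rule names Sirt1 and the other sirtuins, then 19 fixed genes of uterine biology and aging. It adds the 12 genes with the highest and the 12 with the lowest log2 ratio at or above the median mean level, and the 12 smallest p-values in each direction. Unnamed transcripts, pseudogenes and histone or ribosomal copies were left out of those parts. Up to 4 members of each list with the smallest p complete the rule. The median level was that of the listed genes, 109 normalized counts, because no level is given for the others. Other genes were chosen after their values were seen, and the text says so.

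The design fixed a count model for counts per sample. With only the authors' comparison, their FDR was used as deposited, as the design provided. The direction of each list was tested by its median log2 ratio among 10000 random lists of listed genes, of the same size and matched on deciles of mean level. This test is two-sided, describes genes and not animals, and was run for the 27 lists with at least 3 listed members. The share of listed members was compared with the other tested genes by Fisher's exact test, two-sided, counting each unlisted member as tested. That choice makes an excess harder to call, while a shortage may also reflect members that were not tested. Both were adjusted by the Benjamini-Hochberg method over their lists. Counts adjusted over the list alone could not be given, since unlisted genes have no p. On 200 simulated lists of 12 with no direction, 5.5% passed an unadjusted 0.05, and of 200 lists of 12 with at least 10 higher members drawn from the 8348 listed genes, 44.5% did, so a missed call says little. The share test passed 4% of simulated lists of 24 with no excess and 99% of those with 80% listed.

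Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the FDR limit, the adjustment, the fold limit, a filter on mean level, the 95% limits, the highest library and the scaling. The value without the highest library was computed from the maximum and the group means, taking that library to be in the higher group. Differences between medians of marker lists were tested with 100000 permutations and given bootstrap 95% intervals from 10000 draws, both over genes.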

Results

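Total RNA of the uterus was compared between 6 mice with a uterus-specific deletion of Sirt1, a NAD-dependent deacetylase, and 6 floxed controls on gestational day 3.5, before embryo attachment. The question was which uterine transcripts differ when Sirt1 is deleted. Values are normalized counts and ratios from the authors' deposited table, which gives means per genotype and no library totals, so depth per library is unknown. For gene lists, an adjusted p with no test named is that of the random-list test of direction.

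Sirt1 itself is not in the authors' deposited table, so the deleted gene could not be used to check the labels. A value over the whole gene need not fall when part of it is deleted. Sirt2, Sirt3, Sirt4 and Sirt6 are not listed either. In the authors' deposited table, Sirt7, a nucleolar deacetylase, was 1.81-fold higher in Sirt1-KO (95% limits 1.58 to 2.07, adjusted p = 9.94e-17), and Sirt5, a mitochondrial deacylase, was 1.65-fold higher (1.41 to 1.91, adjusted p = 6.98e-10).

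The 2 genotypes differed over a large part of the transcriptome. Of 21344 tested genes, the authors' deposited table lists 8348 (39.1%), of which 3715 were higher and 4633 lower in Sirt1-KO. The last listed gene has rank 12065 by p, so at least 3717 further genes passed the FDR limit with a smaller fold. The median fold in the authors' deposited table was 2.18 among genes higher and 2.52 among genes lower, and 245 genes were higher and 473 lower by at least 5-fold. Higher genes made up 44.5% of the 8348 genes as deposited. Scaling the ratios to equal totals of listed protein-coding genes, a shift of 0.50 on the log2 scale, is too small to turn any gene listed at 1.5-fold or more, and left 6581 genes at 1.5-fold or more, 29.6% of them higher. Scaling to equal totals of all listed genes, ribosomal RNA included, a shift of 1.13, left 5402 genes at 1.5-fold or more, 14.2% of them higher. Counted by direction alone, 1876 genes listed as higher would then be lower, namely those listed as higher by less than 2.19-fold, among them Sirt5, Sirt7 and Esr1. Neither scaling can remove any of the 4633 genes listed as lower. Unlisted genes that would become lower are not counted, so the totals and shares after scaling depend on which genes are listed.

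The genes with the largest falls and rises are those at or above the median level of listed genes (109 normalized counts), without unnamed transcripts and pseudogenes. By the authors' deposited table, Depp1, a FOXO-induced gene on chromosome 6, fell 94.8-fold (95% limits 19.5 to 461) and 58.6-fold without its highest library. Igfbp3, which binds insulin-like growth factors, fell 48.8-fold from a mean of 3542 normalized counts in controls to 72.6 in Sirt1-KO (17.8 to 134, adjusted p = 4.77e-13). Fst, the activin antagonist follistatin, fell 16.4-fold in the authors' deposited table (8.91 to 30.1), as did Cyp1b1, a cytochrome P450 that oxidizes estradiol, by 16.3-fold (9.15 to 29.2). Lrat, which esterifies retinol, fell 14.3-fold and Mest, an imprinted gene, 14.5-fold (9.76 to 21.5), per the authors' deposited table. Falls of Clca3a1 (17.1-fold) and Dlg2 (15.3-fold) stand beside those of Atp6v0d2, Spink1, Atp13a4 and Slc46a2 in the authors' deposited table. These last genes fell 28.7-fold, 20.3-fold, 19.6-fold and 13.4-fold, and 16.1-fold, 12.02-fold, 12.2-fold and 8.66-fold without the highest library of each.

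Bcl2l15, a BCL2 family member on chromosome 3 from 103832601 to 103854618, rose 29.4-fold in the authors' deposited table (95% limits 17.4 to 49.7, adjusted p = 2.57e-34), from 13.7 to 402 normalized counts. Unc5cl rose 18.2-fold (9.75 to 33.8), the zinc transporter Slc39a2 16.4-fold (10.8 to 24.9) and the carbonyl reductase Cbr2 14.9-fold (7.65 to 28.9) in the authors' deposited table. The estrogen-induced secreted protein lactoferrin, Ltf, rose 14.8-fold there, and 8.06-fold without its highest library. Fer1l4, Tmem54, Ppp2r2b, Sprr2f, Plch2, Galm and the iodide transporter Slc5a5 rose between 11.2-fold and 14.8-fold in the authors' deposited table. Exons of 5 of these 12 genes and of 4 of the 12 with the largest falls overlap another annotated gene. Among them are Tmem54 with Hpca, Slc39a2 with Mettl17 and Mest with Copg2. Of all 180 named genes that are listed, 63 have such an overlap, including Sirt7, Nos3, G6pdx, Col4a2, Mcm7 and Il11ra1.

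**Figure D1:**
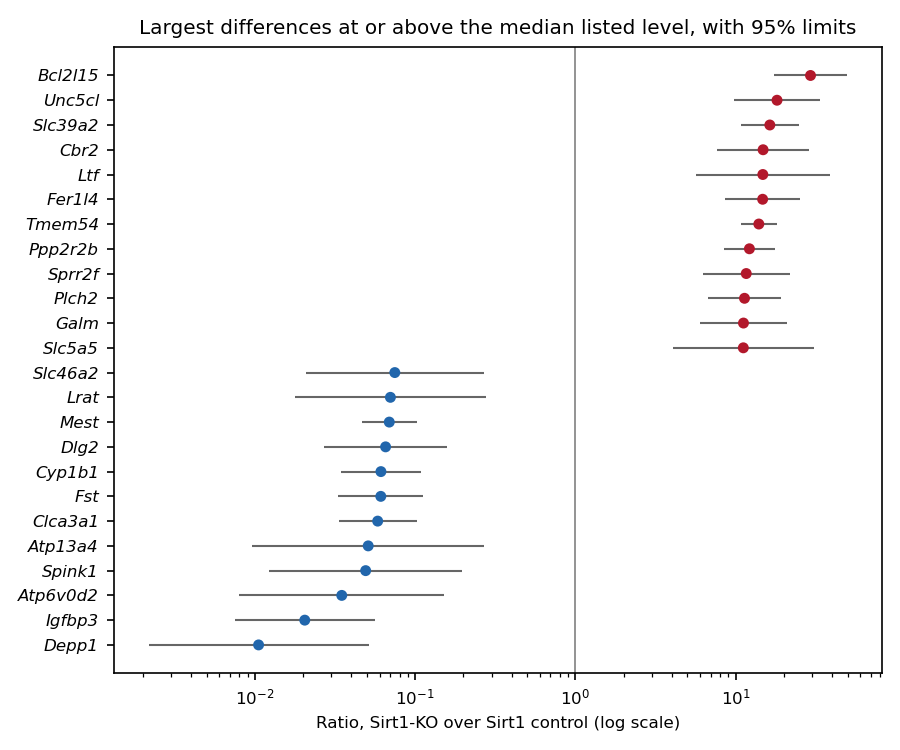
Ratio of Sirt1-KO to Sirt1 control on a log scale for the 12 genes with the largest rise and the 12 with the largest fall in the authors' deposited table among those at or above the median level of 109 normalized counts, unnamed transcripts, pseudogenes and histone or ribosomal copies left out. Points are ratios, red where higher and blue where lower, and bars are the 95% limits, which run from 19.5-fold to 461-fold for Depp1 and from 17.4-fold to 49.7-fold for Bcl2l15.

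The smallest p of the comparison belonged to Armcx4, which fell 5.79-fold (95% limits 5.00 to 6.71, adjusted p = 3.21e-117) in the authors' deposited table. The endothelial genes Emcn, Tie1 and Nos3 fell 9.37-fold, 7.10-fold and 8.07-fold in the authors' deposited table, with Cyyr1 (7.09-fold), Arap3 (5.87-fold), Gimap4 (6.78-fold), Abcg1 (6.03-fold), Nxpe2 (7.09-fold), Frmd4a (4.43-fold) and Myh10 (2.85-fold). Cd38, an enzyme that consumes NAD, fell 7.30-fold there (5.71 to 9.33). Of genes that rose, Tmem54 had the smallest adjusted p (6.07e-83) in the authors' deposited table, with Cracr2b (4.50-fold), Bsn (4.90-fold), Bnipl (5.75-fold), Tmem79 (4.76-fold), Slc9a3r1 (4.16-fold), Chd9 (3.14-fold) and G6pdx, the first enzyme of the pentose phosphate pathway (2.74-fold). Atp9a, Zc3h11a, Acsl5 and Rnh1 rose between 2.04-fold and 2.58-fold in the authors' deposited table.

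Markers of uterine cell types moved in opposite directions. Of 15 epithelial markers, 13 were higher and none lower in the authors' deposited table, with a median log2 ratio of 1.45, and 12 stayed higher when scaled to the total of all listed genes. Keratins Krt8 (3.81-fold, 2.88 to 5.02) and Krt18 (2.73-fold, 2.27 to 3.29), E-cadherin Cdh1 (2.65-fold) and the transcription factor Ehf (4.47-fold) were among them. More epithelial markers were listed than of other tested genes (Fisher's exact test, adjusted p = 0.00109), while their median did not pass against matched random lists (adjusted p = 0.0821), and passed without matching on level (adjusted p = 0.0081). Of 15 stromal markers, 12 were lower in the authors' deposited table (median log2 ratio -1.65), including the growth factor receptor Pdgfra (5.98-fold), Thy1 (5.54-fold), Vim (3.85-fold) and Mmp11 (2.71-fold). Stromal markers passed the random-list test (adjusted p = 0.0018) and the share test (adjusted p = 0.00844), the latter not at an FDR of 0.01 (adjusted p = 0.0562).

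All 14 blood endothelial markers fell in the authors' deposited table, between 5.25-fold and 11.99-fold, with a median log2 ratio of -3.05. Pecam1 fell 9.64-fold (7.28 to 12.8) and the angiopoietin receptor Tek 10.8-fold (8.02 to 14.5). Both list tests passed (random lists, adjusted p = 0.00108, and Fisher's exact test, adjusted p = 1.75e-05). In the authors' deposited table, 2 of 7 lymphatic markers were listed, Flt4 (5.59-fold lower) and Pdpn (2.59-fold lower), and 3 of 14 smooth muscle markers, Synm, Des and Synpo2, lower by 2.78-fold, 2.03-fold and 1.81-fold, and neither list passed a test.

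Listed leukocyte markers were mostly lower. Of 15 markers of macrophages and dendritic cells, 13 fell and Cd14, the lipopolysaccharide co-receptor, rose (3.36-fold) in the authors' deposited table, where Itgax fell 5.92-fold, H2-Ab1 3.36-fold and Cd74 3.11-fold. The share of this list passed (Fisher's exact test, adjusted p = 0.000134) and its median did not (adjusted p = 0.0897). Of 15 markers of T and natural killer cells, 7 fell and 8 were not listed in the authors' deposited table, with a median log2 ratio of -2.67 that passed the random-list test (adjusted p = 0.00108). The members that fell include Klrb1c (9.32-fold), the perforin gene Prf1 (9.23-fold), Il2rb (7.28-fold) and Ncr1 (6.06-fold), while Cd3e, Cd4 and Cd8a are not listed. Only 2 members lie above the lower quartile of level, too few for a test there. The share of listed members in this list did not pass (Fisher's exact test, adjusted p = 0.912). B and plasma cell markers (3 lower and 1 higher of 9), neutrophil markers (1 and 1 of 11), the mast cell marker Kit (1 of 8, 4.21-fold lower) and 3 hemoglobin genes of 7 erythroid markers passed no list test.

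Markers of other tissues were seldom listed, and of the lists in this paragraph only the adipocyte list passed a test, at the FDR of 0.05 and not at 0.01. The authors' deposited table holds 2 of 7 mesothelial markers (Wt1, 3.42-fold lower, and Upk1b, 2.27-fold lower and 1.42-fold without its highest library) and 1 of 10 ovarian markers, Inha (3.16-fold lower). Of 10 markers of oviduct and ciliated epithelium, Ovgp1 was 4.77-fold higher and Ccdc39 and Tekt1 lower in the authors' deposited table. Among 12 embryo and trophoblast markers, Elf5 (8.54-fold) and Krt18 were higher and Eomes (5.05-fold) and Tfap2c (4.09-fold) lower, and Krt18 and Eomes also belong to the epithelial and natural killer lists. Of 9 nerve markers, Plp1 was higher (1.70-fold) and Scn7a lower (3.30-fold) in the authors' deposited table. None of 10 adipocyte markers was listed, fewer than of other tested genes (Fisher's exact test, adjusted p = 0.0302), and this call was lost at an FDR of 0.01 (adjusted p = 0.0656).

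**Figure D2:**
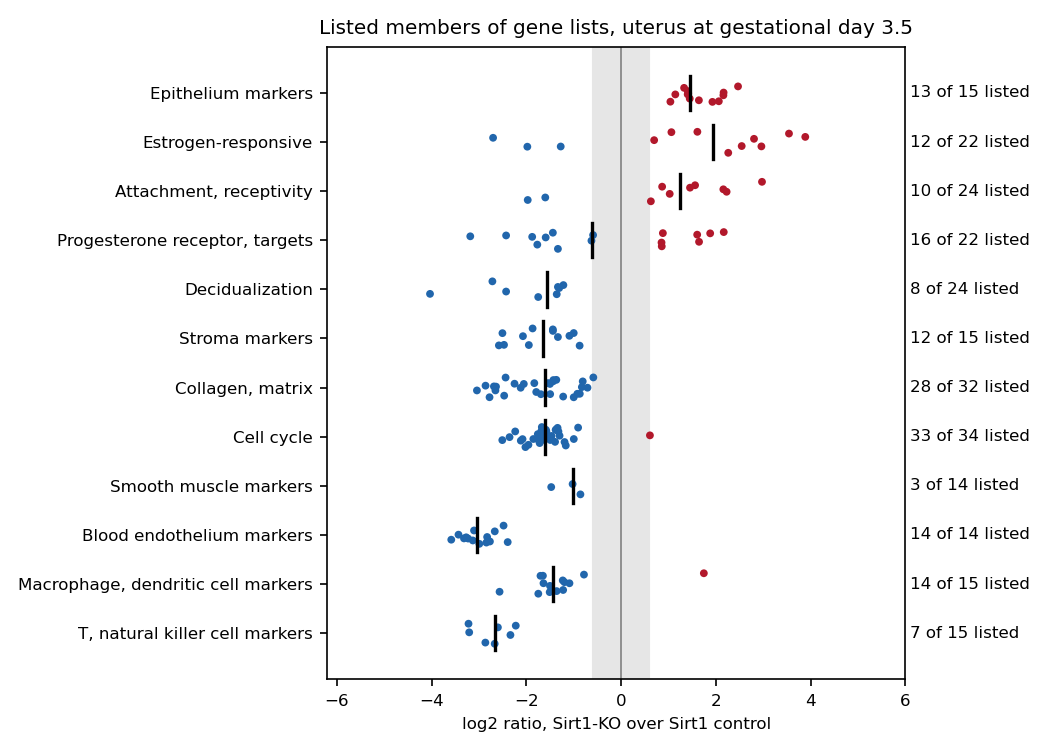
Log2 ratio of Sirt1-KO to Sirt1 control for each listed member of 12 fixed lists, with 1 point per gene, red where higher and blue where lower. Black bars are medians, the gray band holds folds under the table's limit of 1.5, and numbers at the right give listed members, such as 14 of 14 endothelial markers with a median of -3.05.

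Neither the progesterone receptor Pgr nor its epithelial target Ihh is listed. The estrogen receptor Esr1 was 1.62-fold higher (1.40 to 1.88, adjusted p = 5.98e-10) in the authors' deposited table. Of 22 genes in the estrogen-responsive list, 9 were higher and 3 lower there. Their median log2 ratio of 1.94 passed the random-list test (adjusted p = 0.00108), and 7 stayed higher when scaled to the total of all listed genes. Beside Ltf, the 9 higher genes include Sprr2f (11.7-fold) and the mucin Muc1 (2.09-fold). The growth factor Igf1, also in this list and made in stroma, fell 3.94-fold (2.55 to 6.08). The epithelial markers moved in the same direction as this list. The share of listed members in the estrogen-responsive list did not pass (Fisher's exact test, adjusted p = 0.452). Of 22 progesterone receptor genes and targets, 7 were higher and 9 lower in the authors' deposited table, more listed than of other genes (Fisher's exact test, adjusted p = 0.00773), with no common direction past the threshold (adjusted p = 0.0897). Sox17, an epithelial transcription factor, rose 3.05-fold and the co-chaperone Fkbp4 1.84-fold, whereas Hand2, a stromal factor that restrains epithelial growth, fell 5.38-fold (4.03 to 7.17) and Hoxa10 2.52-fold (2.01 to 3.16) in the authors' deposited table. Nr2f2, another stromal factor, was 1.51-fold lower there, and 1.47-fold lower without its highest library.

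Genes of attachment and decidualization were also listed in part. Msx1, a homeobox factor that normally declines before attachment, rose 4.47-fold (2.97 to 6.72), and so did the prostaglandin synthase Ptgs1 (7.86-fold, 5.42 to 11.4), Klf5 (2.95-fold) and Vangl2 (2.04-fold) in the authors' deposited table. Of 24 attachment genes, 8 were higher and 2 lower (adjusted p = 0.0897), and Lif, the cytokine needed for attachment, is not listed. Decidualization, the change of stromal cells that supports the embryo, was represented by 8 of 24 genes in the authors' deposited table. Each of the 8 fell (median log2 ratio -1.55, adjusted p = 0.0606), including Fst, Bmp2 (3.36-fold, 1.83 to 6.16) and Il11ra1 (2.47-fold), and with the mean in place of the median the list passed (adjusted p = 0.00154). The share of listed members in this list did not pass (Fisher's exact test, adjusted p = 0.912). Stromal markers, with which this list shares 1 gene, fell with it by a median log2 ratio of -1.65. Wnt4 and Foxo1 are not listed. Among 14 gland genes, the authors' deposited table has Pax8 (1.68-fold) and Fxyd4 (4.77-fold) higher and Spink1, Lgr5 (4.59-fold) and Gpx3 lower (adjusted p = 0.0606), and Foxa2 is not listed.

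Cell cycle genes fell together. Of 34 members, 32 were lower and Tyms higher in the authors' deposited table, with a median log2 ratio of -1.60. The proliferation marker Mki67 fell 3.88-fold (2.42 to 6.22), cyclin Ccne1 5.68-fold (3.81 to 8.49), the replication helicase genes Mcm5 5.11-fold and Mcm7 2.46-fold, and E2f1 4.33-fold in the authors' deposited table. Both list tests passed (random lists, adjusted p = 0.00108, and Fisher's exact test, adjusted p = 2.57e-11). Stromal markers fell with this list, by a median log2 ratio of -1.65. Top2a is the member not listed.

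Extracellular matrix genes fell as a group. Of 32 members, 28 were lower and none higher in the authors' deposited table (median log2 ratio -1.62, random lists, adjusted p = 0.00108, and Fisher's exact test, adjusted p = 3.66e-07), in the same direction as the stromal markers, of which 2 are also in this list. Versican, Vcan, fell 8.24-fold (5.77 to 11.8), tenascin Tnc 7.26-fold (5.48 to 9.63), the basement membrane collagen Col4a2 6.29-fold (4.41 to 8.96) and laminin Lamb1 2.83-fold in the authors' deposited table. Col1a1, the main fibrillar collagen, was 1.501-fold lower (1.07 to 2.10, adjusted p = 0.0338) and 1.42-fold lower without its highest library. Of 22 genes of TGF-beta signalling, 8 fell and 2 rose in the authors' deposited table (adjusted p = 0.0606, and 0.0288 among genes above the lower quartile of level). All 3 ligand genes fell, Tgfb1 4.70-fold, Tgfb2 4.36-fold and Tgfb3 3.54-fold, and the receptor Acvr2a rose 1.95-fold there.

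Listed senescence genes were mostly lower, without passing the test of direction. Of 24 members, 8 were lower and Cdkn1b, a cell cycle inhibitor, higher (1.68-fold) in the authors' deposited table (median log2 ratio -1.01, adjusted p = 0.244, and 0.00154 with the mean in place of the median). The largest fold in the list was that of Igfbp3, 48.8-fold lower, and the mean gives such a member more weight than the median does. Cdkn1a and Cdkn2a, cell cycle inhibitors that also belong to the senescence list, are not in the authors' deposited table. Mmp2 fell 5.19-fold (3.60 to 7.49) and Trp53 2.01-fold (1.77 to 2.28) in the authors' deposited table. Of 22 targets of p53, 8 were higher and 3 lower there (adjusted p = 0.298), with Sesn2 3.71-fold, Ddb2 2.63-fold and Mdm2 1.53-fold higher and Phlda3 2.65-fold lower.

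Few genes of mitochondrial respiration were listed. Cycs, the gene of cytochrome c, was the only 1 of 25 members in the authors' deposited table (1.54-fold lower, and 1.46-fold without its highest library), fewer than of other tested genes (Fisher's exact test, adjusted p = 0.000634). None of 28 cytosolic ribosomal protein genes was listed (adjusted p = 1.71e-05 by the same exact test). Ppargc1a is not listed, and of 22 genes of PGC-1 alpha and fatty acid oxidation 4 were higher and 2 lower in the authors' deposited table, with Esrra (1.89-fold), Cs (1.69-fold), Acox1 (1.67-fold) and Ucp2 (1.61-fold) higher. Oxidative stress defence had 3 higher and 2 lower of 23, with Prdx3 (1.96-fold), Gclc (1.80-fold) and Gsr (1.71-fold) higher and Gpx3 lower (3.49-fold) in the authors' deposited table. Among 20 genes of sirtuins and NAD metabolism, 3 were higher and 4 lower, including Cd38 and Parp1 (1.80-fold lower). These last 3 lists passed neither list test.

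The remaining lists had members in both directions and passed neither list test. Of 24 NF-kB and inflammatory genes, 5 were higher and 7 lower in the authors' deposited table, with Csf3, a granulocyte growth factor, 8.25-fold higher (5.65 to 12.05) and Icam1 4.74-fold, Nfkbie 3.44-fold and Tnfrsf1a 2.61-fold lower, and Nfkb1 is not listed. Of 25 interferon genes, 9 were higher and 5 lower there, with Irf7 (3.03-fold), Stat2 (1.96-fold) and Irf9 (1.55-fold) higher and Ifit2 (2.55-fold) lower. Autophagy and lysosome genes had 6 higher and 2 lower of 24, with Becn1 2.02-fold, Gabarapl2 1.64-fold and Lamp2 1.63-fold higher and Ulk2 1.80-fold lower in the authors' deposited table. Clock genes had 3 higher and 3 lower of 18, with Rorc (2.35-fold) and Per2 (1.63-fold) higher and Nfil3 (1.96-fold) and Cry1 (1.54-fold, and 1.496-fold without its highest library) lower. Of the 27 lists with a direction test, 6 passed, 1 above and 5 below random lists, and the adjusted p of the other 21 ran from 0.0606 to 0.935. A p of 0.0002 before adjustment is the smallest that 10000 random lists can give.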

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

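Signals outside the messenger RNA comparison stood out because the authors' deposited table lists them above control. The test on removal of ribosomal RNA, and the check of what the bound on the receptor genes can exclude, were chosen after the result was seen. Both tests on genomic DNA were set before their values were computed. All genes in this part were chosen after their values were seen.

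The ribosomal RNA gene CT010467.1 was 3.44-fold higher in Sirt1-KO (95% limits 2.28 to 5.19), and the 7SL RNA gene Rn7s1, part of the signal recognition particle, 3.59-fold higher (2.39 to 5.40) in the authors' deposited table. Rn7s1 and Rn7s2 are near-identical copies whose reads cannot be separated. With these RNAs, the listed normalized counts summed to 2.19 times as much in the mean Sirt1-KO library as in the mean control library, and listed protein-coding genes to 1.42 times.

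All 71 listed genes of small nuclear, small nucleolar and small Cajal body RNAs were higher in the authors' deposited table (median 2.58-fold), and 46 stayed higher when scaled to the total of all listed genes (median log2 ratio 0.24). That total holds much ribosomal and 7SL RNA, so this scaling takes off part of the signal itself. If genomic DNA added reads in proportion to annotated exon length, its rise per kilobase here would be near that at silent receptor genes. The median rise was instead 469 normalized counts per kilobase, against at most 3.86 at the receptor genes that were higher. Reads that run past short genes, or that are shared between gene copies, were not allowed for. Weaker removal of ribosomal RNA stays open. The share of these genes that were higher (100%) restates why they were chosen, and the ribosomal RNA gene was itself higher. A different yield of short or nuclear RNA and the genotype were not tested.

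Of 84 listed olfactory and vomeronasal receptor genes, 81 were higher in Sirt1-KO (median 3.19-fold), and 74 when scaled to the total of all listed genes, at a median mean level of 6.42 normalized counts. Genomic DNA may contribute. It would raise other genes of the same low level, of which 49.7% of 652 listed were higher, less than the 60% set beforehand as the bound against it. That bound was set too high, since the median rise per kilobase of the receptor genes would lift 21.1% of the 630 such genes with a known length to 1.5-fold, so the test cannot exclude it. Of unprocessed pseudogenes 22 of 29 were higher, and of processed ones 221 of 365, against 41.7% of listed protein-coding genes, while of the unverified transcripts annotated as TEC 251 of 648 (38.7%) were higher, so these classes point both ways. The genotype stays open as well.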

How the results depend on the processing

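No paired analysis was possible because the table gives no value per library, although the labels number the libraries 1 to 6 in both groups. For the same reason no other split of the libraries, other count model, scaling method, pseudocount or set test with an estimated correlation could be run. An FDR limit of 0.1, centring on the median of all genes and a background in the same decile of level were not run, since unlisted genes have no values. The lower fold limit of 1.5 and a new adjustment over listed genes removed no gene by construction and say nothing about stability. Sirt1 has no value under any setting. The 95% limits, the highest library and the scaling were alternatives chosen after seeing the data. Stricter limits lower the counts by construction. Bonferroni adjustment gave 4889 genes, 2175 higher and 2714 lower, and a 2-fold limit 5562, of which 2202 were higher. With the nearer 95% limit at 1.5-fold or more, 5071 genes were left, 2052 higher and 3019 lower. Scaling to the listed protein-coding total left 1948 higher genes, because it lowers every log2 ratio by 0.50. Neither this scaling nor the next can remove a gene listed as lower, and unlisted genes are not counted. Scaling to the total of all listed genes left 5402 genes, 769 of them higher, because it lowers every log2 ratio by 1.13. It turned 27 named genes and the medians of 7 lists, none of which had passed the direction test. The log2 ratios of those genes became Rnh1 -0.10, Acsl5 -0.064, Sirt5 -0.41, Sirt7 -0.28, Esr1 -0.43, Fkbp4 -0.25, Muc1 -0.068, Vangl2 -0.10, Pax8 -0.38, Cdkn1b -0.38, Mdm2 -0.52, Acvr2a -0.17, Acox1 -0.39, Cs -0.38, Ucp2 -0.45, Esrra -0.21, Prdx3 -0.16, Gsr -0.36, Gclc -0.28, Irf9 -0.49, Stat2 -0.16, Becn1 -0.11, Lamp2 -0.43, Gabarapl2 -0.42, Per2 -0.43, Plp1 -0.37 and Gm26917 -0.058. The count above the lower quartile of level (6261) was set by construction, because the quartile is that of the listed genes. Counts at an FDR of 0.01 (7478 genes) and without the highest library (7791) stayed within 1.5 times the main count. The last of these is a limit on the fold alone, with the deposited FDR kept and the highest library taken gene by gene, and does not test the calls again. By it, 557 genes fell under 1.5-fold and 0 changed direction. Lists past the direction test numbered 6 as deposited and 6 to 9 over the alternatives. Above the lower quartile of level the 6 differ, since the T and natural killer list has 2 members left and no test, and TGF-beta signalling passed. Lists with an excess of listed members numbered 7, and 6 at an FDR of 0.01. Leaving out the fold limit and the scalings, which cannot move a list test, 141 list results were recomputed. Of these 134 stayed on their side of the threshold, 5 passed it newly and 2 lost it (the shares of stromal and adipocyte markers at an FDR of 0.01). Reversal was scored only for the 6 lists past the direction test, and 0 reversed. Among lists that had not passed, medians changed sign above the lower quartile of level for sirtuins and NAD metabolism (-0.85 to 0.66) and embryo and trophoblast markers (-0.29 to 1.45). Of the 180 named genes, 38 did not pass under Bonferroni adjustment and 6 did not pass at an FDR of 0.01. What depth limits cannot be stated, because the depth of each library is unknown.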

Other observations

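The gene groups in this paragraph and the next were chosen after their values were seen, so they are given as counts with no test. Of 17 genes of blood vessel signalling, 12 were lower and Notch1 higher in the authors' deposited table (median log2 ratio -1.79), beside endothelial markers with a median of -3.05. The apelin receptor Aplnr fell 11.9-fold (95% limits 7.87 to 18.1), Vwf, a clotting factor of endothelium, 9.84-fold and Notch4 4.18-fold. Of 17 genes of epithelial salt and water transport, 7 were higher and 3 lower (median log2 ratio 1.30), beside epithelial markers with a median of 1.45. The sodium pump subunits Atp1b1 and Atp1a1 rose 5.70-fold and 2.22-fold, the sodium channel subunit Scnn1a 4.53-fold, its kinase Sgk1 4.54-fold and the chloride channel Cftr 3.05-fold in the authors' deposited table.

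Of 20 imprinted genes, 11 were lower and 2 higher in the authors' deposited table, where 55.5% of all listed genes were lower. The median log2 ratio of the listed imprinted genes was -1.17, against -0.82 for random lists matched on level. H19, a non-coding RNA, fell 10.4-fold (7.01 to 15.5), Rtl1 7.72-fold, Meg3 4.62-fold and Grb10 2.13-fold there. Of 52 listed histone genes, 50 were lower (median 3.50-fold). Many histone genes are near-identical copies whose reads can be split between them. Each of the 9 listed Gimap genes, GTPases of immune cells, was lower.

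In the marker pattern weighed next, the tests on gene length and GC content were set before their values were computed, and the tests on dilution and on the highest library, and both tests on the cell cycle genes, were chosen after the result was seen. Epithelial markers were higher, and stromal and endothelial markers lower, with a gap of 4.50 on the log2 scale between the epithelial and endothelial medians (bootstrap interval 4.21 to 5.18). More epithelium would dilute other cell types alike, but the endothelial median lay below the stromal one by a difference of -1.39 (interval -1.89 to -0.71, permutation p = 3e-05). Intervals and permutation p-values in this paragraph and the next treat genes as independent and hold no spread between animals. Of 14 smooth muscle markers the 3 listed were lower, by 1.81-fold to 2.78-fold, the direction dilution gives. The 11 not listed were not tested, above the FDR limit or under the fold limit, whereas 12 of 15 stromal markers were listed as lower. This smooth muscle share of 21.4% did not differ from that of other tested genes (Fisher's exact test, adjusted p = 0.567), so these markers do not decide on dilution. With the trend over gene length taken off, the gap was 4.54 (4.12 to 5.16), with that over GC content 4.62 (4.20 to 5.16), and without the highest library 4.37 (4.10 to 5.03). Over listed genes, the decile medians taken off ran from -0.88 to 0.84 for length and from -0.86 to 0.63 for GC content. Differences of that size are smaller than the gap, so neither correction could have closed it. A hypothesis that stays open is that the share or the state of endothelial and stromal cells differs by genotype, and a difference in the dissection of the 2 groups was not tested.

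Cell cycle genes were lower with a median log2 ratio of -1.47 after the highest library was left out (bootstrap interval -1.58 to -1.27), so a single library may be set aside as the whole cause. Their median differed from that of the stromal markers by 0.051 (interval -0.42 to 0.68, permutation p = 0.811), and 0 genes are in both lists. Endothelial markers and T and natural killer markers fell as well (median log2 ratios -3.05 and -2.67). Fewer stromal cells, fewer cells of another type and less division per cell cannot be told apart here, because the table has no values by cell type.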
